A study of Mus musculus with 13 samples.

How the data were processed

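RNA was measured in 13 libraries of mouse haematopoietic stem cells (HSCs), each made from 100 cells sorted from the bone marrow of recipients of a single transplanted cell. Per the labels, polyadenylated RNA was converted to cDNA with a Smart-seq+ protocol and made into Nextera XT libraries. Per the submitters' processing notes, Trimmomatic, FastQC, STAR and featureCounts were used with the mouse build mm9. Their versions, settings, strand mode and annotation were not given in the sources used here. The deposited table holds raw read counts per gene symbol, and the values themselves are whole numbers whose totals differ between libraries, so they were treated as counts that the authors had not normalized. The protocol as labelled carries no molecular identifiers, so counts include PCR copies and count-based floors cover counting error only. Without a stated strand mode, reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as Phf11d, Ctla2a, the MHC genes and the ribosomal protein genes, are uncertain to the extent that reads were shared. The reference held here is of a later mouse build, so no coordinates are printed and it was used only for transcript length and GC content.

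The table holds 24015 gene symbols and 92 ERCC spike-in rows. Spike-in rows were left out of library sizes and of gene and list tests, and their share was compared between groups on its own. Gene counts per library ran from 16371921 to 41367057 and 11233 to 12310 genes had a count. At the shallowest library the floor of 3 counts corresponds to 0.183 CPM, the count scaled to the library's total. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between replicates, over genes with at least 20 counts, was 163. The labels do not say that replicates come from separate recipients, so p-values measure only the spread between these libraries, which may be technical in part.

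Groups were taken from the labels: 4 MUL-HSC, 6 PEM-HSC and 3 PLT-HSC libraries. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 12536, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation was fitted to all 13 libraries with a term per group, so that the 3 comparisons share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.993 for the common dispersion and 0.624 at the median gene. Fold changes are given on the log2 scale with the standard error (SE). For a group with all libraries at 0, the fold is given as a bound against 3 counts over that group. Such a bound covers the counting of reads only, so the difference between the cells may be smaller. Setting such genes to their bound left the median of every called list as it was.

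There were 30 gene lists, drawn up from general knowledge before the data were examined. They cover blood lineages, HSC identity, genes reported as higher in aged HSCs, cell cycle, quiescence, immediate early, interferon, inflammatory, MHC class II, metabolic, ribosomal, histone, Hox and surface genes, and markers of other cell types. Lists with at least 5 tested members, 24 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at the preset inter-gene correlation of 0.01, and again with the correlation estimated per list. The fry test of limma was an alternative. For each list, members were also adjusted over the list alone. The lists share genes: the aged-HSC and HSC identity lists share 5, and the aged-HSC and megakaryocyte and platelet lists share 4. The libraries' mean log2 CPM over each list was compared by two-sided exact permutation tests.

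Named genes followed a rule fixed before the data were examined. For each comparison and direction it takes up to 10 called genes with the smallest adjusted p whose CPM did not overlap between groups, filled to 3 by unadjusted p where fewer qualified. Symbols that are gene models only, such as Gm followed by digits or names ending in Rik, were left out of this ranking. For each list it takes up to 4 called members, or the 2 highest-expressed ones as values only, and it adds 11 sort and reporter genes. Members that passed only when adjusted over their list alone were chosen after their values were seen.

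The model was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed in 1 group and the other genes of the cell cycle list raised 2-fold in that group. For PLT-HSC against MUL-HSC, of 12198 simulated genes tested, 2% of the genes changed 2-fold, 32% of those changed 4-fold, 52% of those changed 8-fold and 58% of those changed 16-fold were called. For PEM-HSC against MUL-HSC, of 12175 simulated genes tested, the shares were 10%, 44%, 58% and 66%. Of the genes called there, 7 of 84 and 4 of 96 had not been changed. Each share is of 50 genes in a single draw. The real comparisons called 6 and 1 genes, so the adjustment for multiple testing was stricter there. The shares may therefore overstate what could be called in the real data. A change of 2-fold in a single gene was therefore mostly below what these libraries can resolve.

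Alternatives set before the data were examined were RLE and upper quartile normalization, no filter and a filter of at least 10 CPM in 3 libraries, no robust estimation, a replicate block, the number of detected genes as a covariate, a fold limit of 2, a fit of only the groups compared, voom with sample weights, DESeq2 1.42.0, both other forms of the gene list test, and leaving out each library in turn. After the data were seen, a fit without MUL-HSC replicates 1 and 2 and a list test with GC and length trends removed were added. GC content and length were matched for 95.3% of tested genes. Correlation between comparisons that share the MUL-HSC libraries was set beside 100 simulations of unchanged groups. These permuted the libraries' deviations from their group means, rescaled for group size, each with a random sign, because deviations within a group sum to 0. Mitochondrially encoded genes are not among the symbols of the table, and the lists for erythroblasts, T and NK cells, mast cells, basophils and eosinophils, stroma and endothelium, and sex-linked genes had fewer than 5 tested members, so these 6 lists were not tested.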

Results

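The study transplanted single Vwf-expressing HSCs into mice and followed the blood that each cell made over 16 weeks. Vwf encodes von Willebrand factor, a clotting protein of platelets and endothelium that is also transcribed in part of the HSC compartment. Recipients fell into 3 patterns: P-restricted reconstitution (PLT-HSC, 3 libraries), PEM-restricted reconstitution (PEM-HSC, 6 libraries), and multilineage reconstitution (MUL-HSC, 4 libraries). From the marrow of these recipients, donor-derived HSCs that did not express Gata1 were sorted, and 100 cells were used per library. The comparisons ask how the transcriptomes of HSCs with different restrictions differ from those of multilineage HSCs and from each other. Gene counts were 16371921 to 41367057 in MUL-HSC, 22913695 to 28013676 in PEM-HSC and 29017378 to 32437607 in PLT-HSC libraries. In 9 exact permutation tests of total counts, detected genes and spike-in reads between groups, the lowest p was 0.0238, for total counts of PLT-HSC against PEM-HSC, which gave 0.214 after Benjamini-Hochberg adjustment.

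Genes behind the sort and the reporter were measured in all 3 groups. Kit, the stem cell factor receptor, stood at 405 ± 191 CPM in PLT-HSC (SD, n = 3), 338 ± 88.5 in PEM-HSC (n = 6) and 314 ± 75.2 in MUL-HSC (n = 4). Ly6a, which encodes Sca-1, stood at 880 ± 678, 728 ± 174 and 485 ± 113 CPM in the same order, and Slamf1, which encodes CD150, at 242 ± 119, 203 ± 59.3 and 89.5 ± 75.3 CPM. Procr, Ptprc and Itga2b averaged 224, 316 and 5.20 CPM in PLT-HSC, 206, 262 and 8.63 CPM in PEM-HSC, and 195, 278 and 8.58 CPM in MUL-HSC. Gata1, the erythroid and megakaryocyte transcription factor used for exclusion, was at 7.63 ± 12.97 CPM in PLT-HSC, 8.51 ± 8.34 in PEM-HSC and 17.0 ± 9.45 in MUL-HSC. Its log2 fold change in PLT-HSC against MUL-HSC, -1.16, was -6.86 without PLT-HSC replicate 3 and -0.547 without PLT-HSC replicate 1. Transcripts of Cd48 and Flt3, whose proteins were also excluded, averaged 25.5 and 15.2 CPM in MUL-HSC, 2.64 and 1.07 CPM in PEM-HSC, and 6.08 and 0.00932 CPM in PLT-HSC, the last below the floor of 3 counts. Of the 11 sort and reporter genes, Vwf was called over all genes, in both comparisons with MUL-HSC, and the other 10 were not called in any of the 3 comparisons.

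PLT-HSC differed from MUL-HSC in 6 called genes, 5 higher and 1 lower. Vwf was 13.2-fold higher, at 134 ± 41.4 CPM (SD, n = 3) against 10.1 ± 3.68 CPM (n = 4), with a log2 fold change of 3.72 (SE 0.45, edgeR adjusted p = 0.00412). Rdh10, a retinol dehydrogenase of the retinoic acid pathway, rose by 5.83 on the log2 scale (SE 0.84, adjusted p = 0.0189), from 2.15 ± 1.70 to 124 ± 68.2 CPM. Phf11d rose by 2.13 (adjusted p = 0.0289), Ctnnal1, which encodes alpha-catulin and marks HSCs, by 2.93 (adjusted p = 0.0487), and Mef2c, a transcription factor of lymphoid and megakaryocytic cells, by 1.33 (adjusted p = 0.0487). Otos, which encodes otospiralin, fell by 2.40 on the log2 scale (SE 0.39, adjusted p = 0.036), from 131 ± 23.8 to 24.8 ± 12.98 CPM. In each of the 6 genes, no PLT-HSC library overlapped a MUL-HSC library, which follows in part from their selection for a difference between the same libraries. Lat and Serpinb1a were next among lower genes by the naming rule. They did not pass, with log2 fold changes of -1.89 (adjusted p = 0.0555) and -3.31 (adjusted p = 0.0593).

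**Figure D1:**
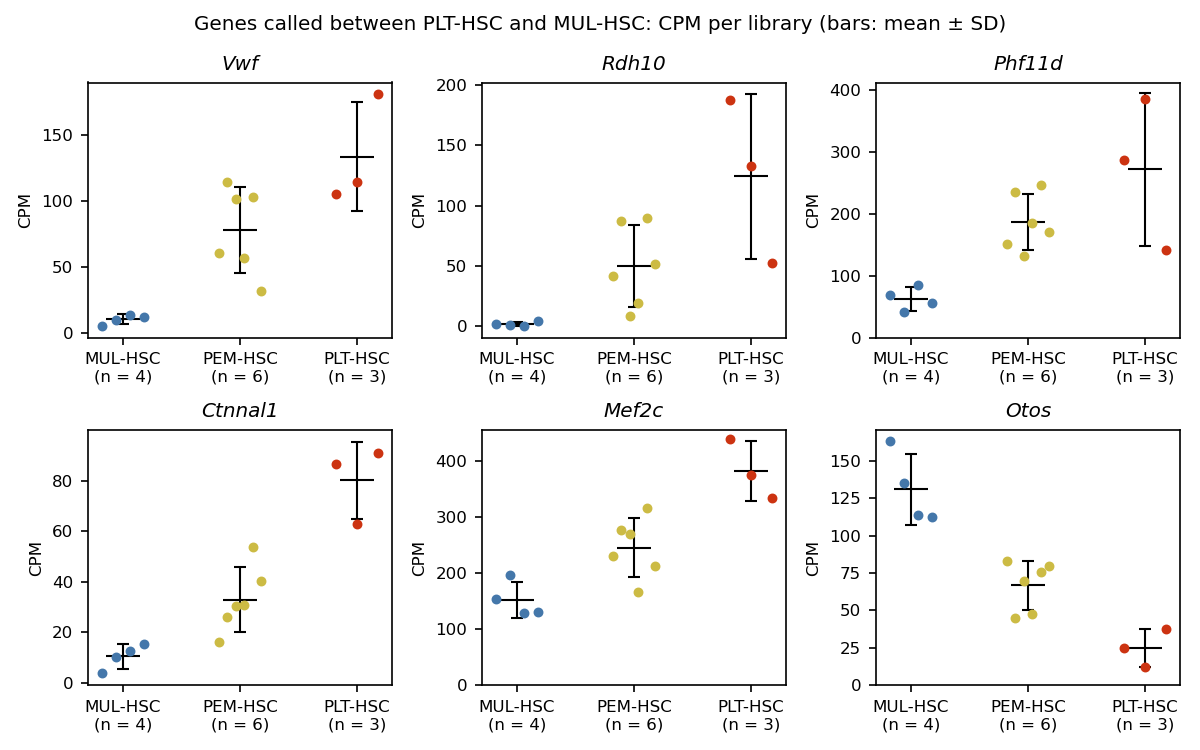
CPM per library (points, vertical axes, linear scale) of the 6 genes called between PLT-HSC and MUL-HSC, in MUL-HSC (n = 4), PEM-HSC (n = 6) and PLT-HSC (n = 3); bars give the mean ± SD. Vwf ran from 5.08 to 13.4 CPM in MUL-HSC, from 31.8 to 114 CPM in PEM-HSC and from 106 to 181 CPM in PLT-HSC.

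The number of called genes in this comparison rested on single libraries. It was 1 without MUL-HSC replicate 1 or PLT-HSC replicate 2, 2 without MUL-HSC replicate 2 or PLT-HSC replicate 1, and 3 without MUL-HSC replicate 4 or PEM-HSC replicate 1, 3 or 6. It was 21 without MUL-HSC replicate 3 and 37 without PLT-HSC replicate 3. The log2 fold changes held their direction over these settings, at 3.43 to 3.89 for Vwf, 5.39 to 6.47 for Rdh10, 1.78 to 2.43 for Phf11d, 2.66 to 3.18 for Ctnnal1, 1.23 to 1.48 for Mef2c and -2.83 to -2.07 for Otos. Over all 24 other settings, the call held in 22 for Vwf, 17 for Rdh10, 15 for Phf11d, 10 for Otos, 9 for Mef2c and 6 for Ctnnal1. Without robust estimation 4 genes were called, and Ctnnal1 and Mef2c were not (adjusted p = 0.0666 for both). Voom called 0 genes, DESeq2 called 286, a fit of only these groups called 1, and 924 genes had an unadjusted p under 0.05. By chance 627 would be expected, but other splits of the same libraries gave 387 to 1501, so 924 is no clear excess. Without MUL-HSC replicates 1 and 2, a setting chosen after seeing the data, 1 gene was called and Vwf was not (log2 fold change 3.38, adjusted p = 0.0923).

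Genes reported as higher in aged HSCs had the smallest camera p of the 24 lists tested between PLT-HSC and MUL-HSC, and were higher in PLT-HSC. Of its 39 tested members, 36 had a positive fold change, the median log2 fold change was 1.62, and 18 were higher when adjusted over the list alone, against 1 (Vwf) over all genes. Among those 18, chosen after their values were seen, were Gstm2, a glutathione transferase (274 against 48.2 CPM, log2 fold change 2.51), Jam2, an adhesion molecule (161 against 34.7 CPM, 2.21), Mt1, a metallothionein (265 against 50.9 CPM, 2.38) and Clu, which encodes clusterin (379 against 14.2 CPM, 4.72). Leaving out 1 library, these log2 fold changes ran from 1.76 to 2.92 for Gstm2, 1.87 to 2.62 for Jam2, 2.02 to 3.44 for Mt1 and 4.05 to 6.31 for Clu. Camera called the list higher (adjusted p = 3.04e-14), and the adjusted p was 0.183 with an estimated correlation. MUL-HSC replicates 1 and 2 had the lowest mean of this list, at -2.47 and -2.34 log2 units from the mean of all libraries, while replicates 3 and 4 stood at -0.07 and -0.56. The PLT-HSC libraries stood at 0.70, 1.47 and 0.002, the last, replicate 3, close to MUL-HSC replicate 3. Without MUL-HSC replicates 1 and 2 the median log2 fold change was 1.10 and camera at the preset correlation still called the list.

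HSC identity genes were also higher in PLT-HSC, with 45 of 52 members positive and a median log2 fold change of 0.68 (camera adjusted p = 7.81e-09, and adjusted p = 0.121 with an estimated correlation). Adjusted over the list alone, 10 members were higher and 1 lower, while over all genes Ctnnal1 passed. The 10 included, chosen after their values were seen, Mecom, a transcription factor needed for HSC maintenance (203 against 76.9 CPM), Mllt3, a regulator of HSC self-renewal (608 against 196 CPM), and Cdkn1c, the cyclin-dependent kinase inhibitor p57 (111 against 33.7 CPM). The lower member was Cd34, a surface protein that falls to low levels in the most primitive mouse HSCs, at 42.6 ± 17.3 CPM in PLT-HSC against 375 ± 208 CPM in MUL-HSC (log2 fold change -3.14, adjusted p = 0.132 over all genes). Interferon response genes were higher as a list, with 41 of 47 positive and a median of 0.57 (camera adjusted p = 1.75e-05, and adjusted p = 0.183 with an estimated correlation). Without PLT-HSC replicate 1 the median was 0.35, with 37 of 47 positive, and camera still called the list. No member of it passed alone, and its most abundant members, Ly6e and Psmb8, stood at 3440 and 1506 CPM in PLT-HSC and at 2315 and 1665 CPM in MUL-HSC.

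Camera called 3 further lists in this comparison. Cell cycle genes were lower, with 35 of 46 negative and a median log2 fold change of -0.66 (adjusted p = 1.73e-06, and adjusted p = 0.618 with an estimated correlation). Their call ended without PLT-HSC replicate 1 (adjusted p = 0.139), where the median was -0.31 with 28 of 46 negative, and without MUL-HSC replicates 1 and 2 (adjusted p = 0.0913), where it was -0.0022 with 24 of 46 negative. Leaving out 1 library, the median ran from -2.05 without PLT-HSC replicate 3 to the -0.31 above. The list mean was -2.89 and -1.39 log2 units from the mean of all libraries in PLT-HSC replicates 1 and 2, and 1.29 in replicate 3. Ribosomal protein genes were higher by a median of 0.14, with 65 of 76 positive (adjusted p = 0.00566, and adjusted p = 0.684 with an estimated correlation), a call that ended without MUL-HSC replicate 4 (0.704, median 0.034) or PLT-HSC replicate 2 (0.682, median -0.0059). The highest median leaving out 1 library was 0.27, without PLT-HSC replicate 1. Hox genes were higher by a median of 0.75, with 12 of 16 positive (adjusted p = 0.031, and adjusted p = 0.618 with an estimated correlation), a call that ended without MUL-HSC replicate 1 (0.363) or 2 (0.0708), or PLT-HSC replicate 1 (0.0511) or 2 (0.314). It also ended without both MUL-HSC replicates 1 and 2 (0.855, median 0.10), with detected genes as a covariate (0.0585) and with voom (0.0501). Leaving out 1 library, the median ran from 0.21 without PLT-HSC replicate 2 to 1.13 without MUL-HSC replicate 4.

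Lineage lists were not called by camera in PLT-HSC against MUL-HSC. Of 37 megakaryocyte and platelet genes 22 were positive (median log2 fold change 0.35, camera adjusted p = 0.292), with Vwf and Sdpr higher and Lat lower when adjusted over the list alone. The platelet genes Pf4 and Gp9 stood at 39.6 ± 14.7 and 75.2 ± 3.96 CPM in PLT-HSC and at 98.2 ± 66.3 and 42.1 ± 15.7 CPM in MUL-HSC. Erythroid genes had a median of 0.32 and granulocyte and monocyte genes of -0.27. Lymphoid-priming genes had a median of -0.00 but a mean of -0.997. Adjusted over that list alone, Mef2c was higher and Flt3 and Blnk were lower. The most abundant erythroid and myeloid members, Car2 and Lyz2, stood at 7270 and 1179 CPM in PLT-HSC and at 4910 and 1422 CPM in MUL-HSC. The other lists not called were those for quiescence and cell cycle inhibitors, immediate early, NF-kB and inflammatory, MHC class II, glycolysis, cholesterol synthesis, oxidative phosphorylation and histone genes, surface receptors and adhesion, sort and reporter genes, and neutrophils, macrophages, B and plasma cells, and mature platelets and megakaryocytes. Their camera adjusted p ran from 0.0765 for oxidative phosphorylation to 0.929 for B and plasma cells. The median, the mean and the test differed in sign for 4 of these 18 lists: NF-kB and inflammatory, glycolysis, cholesterol synthesis, and sort and reporter genes. They had 1 sign for each of the 6 called lists.

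**Figure D2:**
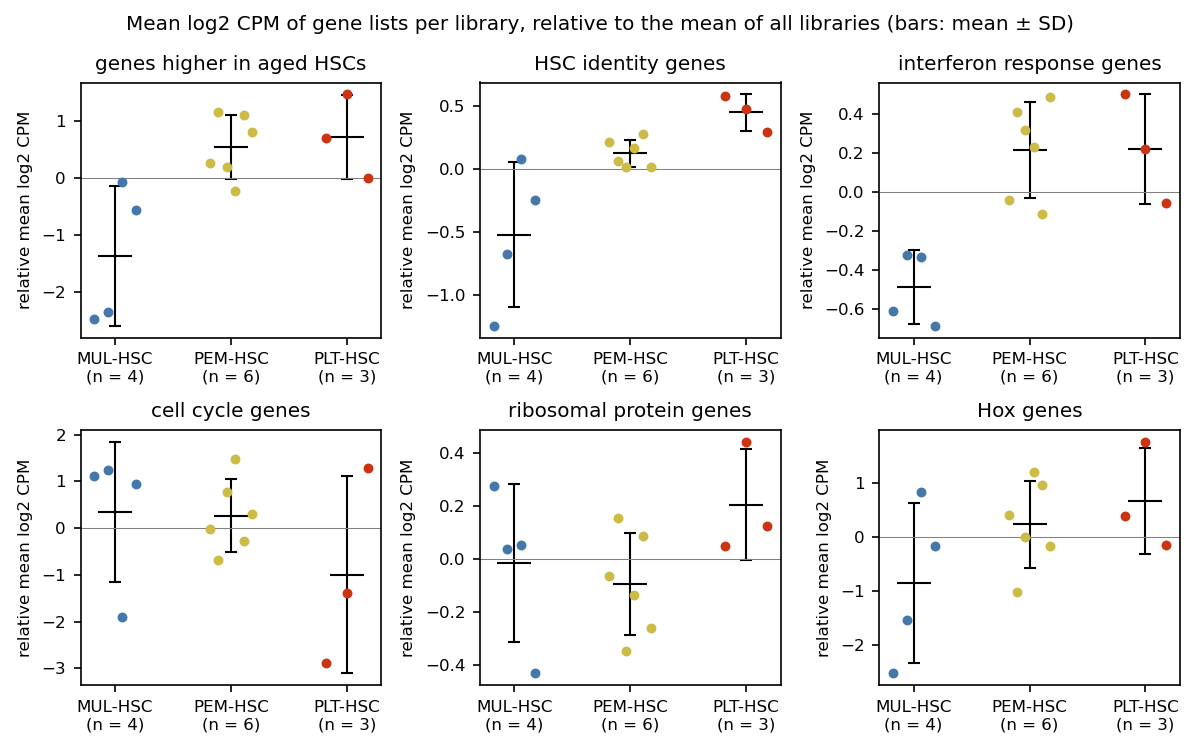
Mean log2 CPM of 6 gene lists per library, relative to the mean of all 13 libraries (vertical axes, log2 units), in MUL-HSC (n = 4), PEM-HSC (n = 6) and PLT-HSC (n = 3); bars give the mean ± SD of libraries. For interferon response genes, every MUL-HSC library lay below every PEM-HSC and PLT-HSC library, but exact tests of the list means did not pass after adjustment over 24 lists (adjusted p = 0.0762 and 0.343). For PLT-HSC against MUL-HSC the unadjusted p of the exact test was the smallest possible, 0.0286. For cell cycle genes, libraries ran from -1.90 to 1.25 in MUL-HSC, -0.69 to 1.49 in PEM-HSC and -2.89 to 1.29 in PLT-HSC.

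PEM-HSC differed from MUL-HSC in 1 called gene. Vwf was 7.69-fold higher, at 78.0 ± 32.8 CPM (SD, n = 6) against 10.1 ± 3.68 CPM (n = 4), with a log2 fold change of 2.94 (SE 0.41, edgeR adjusted p = 0.0234), and every PEM-HSC library lay above every MUL-HSC library. Genes next in rank by the naming rule did not pass. Rdh10 stood at 49.9 ± 33.8 against 2.15 ± 1.70 CPM (adjusted p = 0.117). Gpr4, a proton-sensing receptor, stood at 19.1 ± 13.7 CPM against 0 in all 4 MUL-HSC libraries (adjusted p = 0.126). By the counting of reads alone it was at least 673-fold higher. On the lower side, Cd34 stood at 52.2 ± 37.3 against 375 ± 208 CPM (log2 fold change -2.84, adjusted p = 0.126) and Ctla2a at 343 ± 148 against 1872 ± 1415 CPM (adjusted p = 0.229). Lpxn, which encodes leupaxin, stood at 0 in all 6 PEM-HSC libraries against 17.5 ± 9.45 CPM (adjusted p = 0.319), at least 892-fold lower by the counting of reads alone.

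The call of Vwf in PEM-HSC ended without MUL-HSC replicate 1 (adjusted p = 0.0682), 2 (0.0743) or 4 (0.0979), PEM-HSC replicate 5 (0.0833) or PLT-HSC replicate 2 (0.0519), with log2 fold changes of 2.72, 2.93, 3.06, 2.85 and 2.94. It also ended with detected genes as a covariate (0.0729), with only these 2 groups in the fit (0.0793), with voom (0.416) and without both MUL-HSC replicates 1 and 2 (0.322), with log2 fold changes of 2.97, 2.94, 2.86 and 2.61. The count was 4 without MUL-HSC replicate 3 or PLT-HSC replicate 3 and 2 without PEM-HSC replicate 2 or 3. DESeq2 called 224 genes, and 744 had an unadjusted p under 0.05, where other drawn splits of these libraries gave 329 to 965.

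Genes reported as higher in aged HSCs were higher in PEM-HSC than in MUL-HSC too, with 35 of 39 positive and a median log2 fold change of 1.21 (camera adjusted p = 1.38e-15, and adjusted p = 0.137 with an estimated correlation). Adjusted over the list alone, 4 were higher: Vwf and, chosen after their values were seen, Clec1a (98.4 against 33.4 CPM), Gstm2 (170 against 48.2 CPM) and Prcp (138 against 67.6 CPM). Without MUL-HSC replicates 1 and 2 the median was 0.82. The list mean ran from -0.22 to 1.15 log2 units over PEM-HSC libraries. The lowest of these, replicate 4, lay below MUL-HSC replicate 3 at -0.07. HSC identity genes were higher by a median of 0.49, with 39 of 52 positive (adjusted p = 2.75e-05, and adjusted p = 0.137 with an estimated correlation). Adjusted over the list alone, Ctnnal1, Mllt3, Mycn and Cdkn1c were higher and Cd34 was lower, and the list's call ended without MUL-HSC replicates 1 and 2 (adjusted p = 0.0504, median 0.34). Interferon response genes were higher by a median of 0.45, with 40 of 47 positive (adjusted p = 2.51e-06, and adjusted p = 0.137 with an estimated correlation).

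MHC class II genes, which present antigen, were higher in PEM-HSC by a median log2 fold change of 0.71, with 11 of 13 positive (camera adjusted p = 0.00307, and adjusted p = 0.255 with an estimated correlation). H2-Ab1 (792 against 446 CPM) and H2-Eb1 (277 against 102 CPM) passed when adjusted over the list alone, and Cd74, the invariant chain, stood at 2459 ± 985 against 1005 ± 489 CPM. Without MUL-HSC replicate 2 the median of the list was 1.11. Macrophage markers were higher in the same comparison, with 8 of 9 positive and a median of 1.91 (adjusted p = 0.00473, and adjusted p = 0.137 with an estimated correlation). Their most abundant members were low: Hmox1 stood at 27.8 ± 18.2 against 8.43 ± 7.27 CPM and Axl at 23.2 ± 12.8 against 16.5 ± 14.5 CPM. The median of macrophage markers was 3.48 without MUL-HSC replicate 1. Their call ended without MUL-HSC replicate 3 (adjusted p = 0.0543, median 1.89) and with the filter of at least 10 CPM (0.0775). Oxidative phosphorylation genes were lower by a median of -0.16, with 64 of 78 negative (adjusted p = 0.00147, and adjusted p = 0.812 with an estimated correlation). That call ended without MUL-HSC replicate 1 (0.225, median -0.073) or 2 (0.114, median -0.090), without PEM-HSC replicate 3 (0.0523, median -0.10) and with detected genes as a covariate (0.431), and without both MUL-HSC replicates the direction turned (0.683, median 0.052). The median was also -0.10 without PEM-HSC replicate 6, and it was -0.26 without MUL-HSC replicate 4.

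The lineage lists were not called by camera in PEM-HSC against MUL-HSC either. Megakaryocyte and platelet genes had 19 of 37 members positive (median log2 fold change 0.01, camera adjusted p = 0.918), erythroid genes 15 of 22 (median 0.22, adjusted p = 0.51), granulocyte and monocyte genes 10 of 23 (median -0.10, adjusted p = 0.909) and lymphoid-priming genes 13 of 22 (median 0.15, adjusted p = 0.909). Cd68, a lysosomal protein of monocytes and macrophages, was higher when adjusted over the granulocyte and monocyte list alone, at 79.6 against 14.1 CPM. Among the 18 lists not called, the lowest adjusted p was 0.083, for histone genes, and for 8, among them the megakaryocyte and platelet and the granulocyte and monocyte lists, the median, the mean and the test differed in sign.

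No gene was called between PLT-HSC and PEM-HSC with edgeR, while 467 had an unadjusted p under 0.05 where 627 would be expected by chance. Other splits of these libraries gave 292 to 999 such genes. DESeq2 called 133 genes and voom called 1. Vwf stood at 134 ± 41.4 CPM in PLT-HSC and 78.0 ± 32.8 CPM in PEM-HSC (log2 fold change 0.78, SE 0.39). By the naming rule, the genes with the smallest p on the higher side were Rsrp1, Smg1 and Itch. Rsrp1, a splicing-related gene, stood at 1186 ± 322 against 559 ± 85.5 CPM. Smg1, a kinase of nonsense-mediated decay, stood at 115 ± 5.78 against 42.4 ± 20.3 CPM. Itch, a ubiquitin ligase, stood at 99.1 ± 24.4 against 43.1 ± 11.8 CPM. On the lower side the rule gave Rpusd3 (7.02 ± 2.09 against 36.5 ± 13.6 CPM), Otos (24.8 ± 12.98 against 66.7 ± 16.5 CPM) and Pla2g4c. Pla2g4c stood at 0 in all 3 PLT-HSC libraries against 7.96 ± 7.38 CPM, at least 242-fold lower by the counting of reads alone. Without PLT-HSC replicate 3 the count was 2, and without PLT-HSC replicate 1 it was 1.

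Camera called 4 lists between PLT-HSC and PEM-HSC, and none with an estimated correlation. Ribosomal protein genes were higher in PLT-HSC by a median log2 fold change of 0.24, with 73 of 76 positive (adjusted p = 5.09e-08, and adjusted p = 0.588 with an estimated correlation), a call that ended without PLT-HSC replicate 2 (0.0719), where the median was 0.10 with 53 of 76 positive. Cell cycle genes were lower by a median of -0.33, with 33 of 46 negative (adjusted p = 2.35e-06, and adjusted p = 0.581 with an estimated correlation), a call that ended without PLT-HSC replicate 1 (0.421), where the median was 0.0073 with 23 of 46 positive. It was -0.061 without PEM-HSC replicate 4, -0.15 without PLT-HSC replicate 2 and -1.73, with 42 of 46 negative, without PLT-HSC replicate 3. Cholesterol synthesis genes were lower by a median of -0.38, with 17 of 23 negative (adjusted p = 0.00635, and adjusted p = 0.481 with an estimated correlation), which also ended without PLT-HSC replicate 1 (0.189, median -0.28). HSC identity genes were higher by a median of 0.27, with 44 of 52 positive (adjusted p = 0.00635, and adjusted p = 0.525 with an estimated correlation), a call that ended without PLT-HSC replicate 1 (0.189) or 2 (0.0606), with a median of 0.25 in both. The aged-HSC list was not called here (median 0.33, adjusted p = 0.166), nor were interferon response genes (median 0.11, adjusted p = 0.56). Of the 20 lists not called, 5 had a median, mean and test that differed in sign, erythroid genes among them. No member of any list passed when adjusted over its list alone.

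No list passed in any comparison when the libraries' list means were compared by exact permutation tests and adjusted over 24 lists. These tests could hardly pass, because a single list at the smallest possible p would still fail after adjustment. That smallest p was 0.00476 for PEM-HSC against MUL-HSC and 0.0119 for PLT-HSC against PEM-HSC. The lack of a pass is therefore weak evidence against a difference. In PLT-HSC against MUL-HSC, where 3 and 4 libraries allow no unadjusted p below 0.0286, the adjusted p was 0.343 for the interferon, aged-HSC and HSC identity lists and 0.743 for cell cycle, ribosomal protein and Hox genes. In PEM-HSC against MUL-HSC it was 0.0762 for the aged-HSC and interferon lists, 0.0857 for macrophage markers, 0.0914 for HSC identity, 0.392 for MHC class II and 0.784 for oxidative phosphorylation genes. Between PLT-HSC and PEM-HSC it was 0.143 for HSC identity, 0.393 for ribosomal protein and cholesterol synthesis genes, and 0.468 for cell cycle genes.

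The comparisons of PLT-HSC and of PEM-HSC with MUL-HSC shared 1 called gene, Vwf, which was also the 1 gene called in a test of any difference among the 3 groups (adjusted p = 0.0176). For independent lists of these sizes the expected overlap is 0.000399 genes, but both comparisons use the same MUL-HSC libraries, so unchanged groups would not give that value. Across the 12536 genes, which are not independent replicates, log2 differences of the 2 comparisons correlated at 0.637, against a mean of 0.499 and a highest value of 0.810 in 100 simulations of unchanged groups that share controls. The covariance was 1.004 against 0.626 in the simulations, a difference of 0.378, within the simulated range of up to 1.22. With the MUL-HSC libraries split into separate pairs for each comparison, the mean correlation over the 6 ways was 0.147, against a simulated mean of -0.02 and a highest simulated value of 0.358.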

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

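The explanations weighed here for Vwf, the aged-HSC list and the cell cycle list, and the values used to judge them, were chosen after the results were seen. Among the settings used, the covariate, the estimated correlation, fry and leaving out 1 library were set before the data were examined. Leaving out MUL-HSC replicates 1 and 2 and removing GC and length trends were not. The splits of the libraries were set before their counts were seen. Of 78 group values examined for a library far from the others, 5 were flagged, where chance at 1 in 20 gives 3.9. The criterion was not applied to PLT-HSC, with 3 libraries, so no library of that group could be flagged.

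Cd48 was at 15.8 CPM in PEM-HSC replicate 1 and at 0 in the other 5 PEM-HSC libraries. Flt3 was at 5.20 CPM in PEM-HSC replicate 4 and at most 0.943 CPM in the others, and Serpinb1a was at 189 CPM in that same library against 46.1 to 84.3 CPM in the others. Ctla2a was at 3982 CPM in MUL-HSC replicate 2 against 1007 to 1366 CPM in the other MUL-HSC libraries. The mean of the cell cycle list lay at -1.90 log2 units in MUL-HSC replicate 3 and between 0.944 and 1.25 in the other MUL-HSC libraries. ERCC spike-in reads, which the labels do not mention and no gene or list test used, were present in every library, from 4944 counts in MUL-HSC replicate 3 to 15863 in MUL-HSC replicate 2. Exact tests of their share between groups gave p = 0.798 to 1.

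The higher Vwf of both restricted groups was weighed first. Were it carried in by platelet or megakaryocyte RNA, the mature platelet and megakaryocyte list should move with it, but its median log2 fold change was 0.84 (SD over 11 members 2.37) against 3.72 for Vwf in PLT-HSC, and -0.69 (SD 2.62) against 2.94 in PEM-HSC. Of this list 11 genes are also on the megakaryocyte and platelet list, and the gate excluded Gata1-expressing cells. Its 2 most abundant members moved in opposite directions: Pf4 averaged 39.6, 60.8 and 98.2 CPM in PLT-HSC, PEM-HSC and MUL-HSC, and Gp9 averaged 75.2, 71.2 and 42.1 CPM, with no overlap between PLT-HSC and MUL-HSC. The list was higher in PLT-HSC than in PEM-HSC by fry (adjusted p = 0.0359). In the exact test of library means it reached the smallest p that 84 splits allow (0.0119). Adjustment over 24 lists gave 0.143, which does not count against a difference. Members ran from -1.86 to 5.39 in PLT-HSC and from -4.83 to 3.70 in PEM-HSC, so the highest rose more than Vwf. The list as a set did not rise with Vwf, but with members this spread a contribution of platelet RNA is not excluded, least of all in PLT-HSC. With detected genes as a covariate the log2 fold change of Vwf was 3.78 (SE 0.54) in PLT-HSC and 2.97 (SE 0.44, before 0.41) in PEM-HSC. The PEM-HSC call ended there (adjusted p = 0.0729) through the larger SE and the lost degree of freedom, not through a smaller fold. The donor cells were chosen for Vwf and then sorted by outcome, so a link of Vwf level to reconstitution pattern stays open as a hypothesis that these data cannot separate from differences between recipients.

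The higher aged-HSC list was weighed next. MUL-HSC replicates 1 and 2 may carry part of it, since the median fell from 1.62 to 1.10 in PLT-HSC and from 1.21 to 0.824 in PEM-HSC without them. Of 39 members, 34 and 33 were then still positive, and camera at the preset correlation called the list (larger adjusted p = 0.000119). The correlation of this list was estimated at 0.297, however. With it the camera call was lost even with all libraries (adjusted p = 0.183 and 0.137), so whether these 2 libraries carry all of it stays open. Removing GC and length trends left the larger adjusted p at 7.65e-14. The gate excluded cells with CD48 or Flt3 protein. More progenitors in the MUL-HSC sort could still raise Cd34, Flt3 and Cd48 transcripts and lower the list. Of 6 tests of granulocyte and monocyte, lymphoid-priming and cell cycle lists, 1 was called lower in a restricted group. It was the cell cycle list of PLT-HSC, a call that ended without PLT-HSC replicate 1 (camera adjusted p = 0.139 at the preset correlation). With the other tests not called, the 6 could not decide, so this explanation cannot be told apart from the groups. The adjusted p-values of 0.000119 and 7.65e-14 and the 6 tests assume the preset correlation.

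The lower cell cycle list of PLT-HSC may rest on a few libraries. Without PLT-HSC replicate 1 the larger adjusted p of the 2 comparisons was 0.421, and the median went from -0.66 to -0.31 against MUL-HSC and from -0.33 to 0.0073 against PEM-HSC. Without MUL-HSC replicates 1 and 2 the median against MUL-HSC went to -0.0022 (adjusted p = 0.0913), a larger loss, while that against PEM-HSC stayed at -0.33. Those 2 libraries did not stand apart, as their list means lay at 1.11 and 1.25 log2 units and that of MUL-HSC replicate 4 at 0.944. The library that stood apart was MUL-HSC replicate 3, at -1.90. Without replicate 3 alone, the median against MUL-HSC was -0.95, with 40 of 46 negative. Detected genes as a covariate left the larger adjusted p at 2.01e-09 at the preset correlation, so the call at that setting did not depend on them. With an estimated correlation the call was lost without any covariate (adjusted p = 0.618 against MUL-HSC and 0.581 against PEM-HSC), so the covariate fit does not settle library complexity as a source. PLT-HSC replicate 3 lay at 1.29 log2 units, opposite to replicate 1.

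Other splits of the libraries test how far the counts stand above chance. For PLT-HSC against MUL-HSC, 2 of 35 splits called as many as the real 6 genes (highest other 7), so chance was not excluded. For PEM-HSC against MUL-HSC, 6 of 100 splits called at least 1 gene (highest other 1), for PLT-HSC against PEM-HSC all 84 splits reached the real 0, as any must (highest other 2), and for any group 9 of 100 reached 1 (highest other 2), none of which excludes chance. The overlap of 1 gene was reached by 1 of 100 splits, the real one (highest other 0), the smallest share that 100 splits allow. The splits counted any gene called in both comparisons, not Vwf alone. It was the only one of 11 such tests, 3 of them on separated genes, to stand out, so over the 11 tests chance was not excluded. The overlap was 0 with detected genes as a covariate, with voom, with a replicate block and without some single libraries. As many gene lists were called in 13 of 35 splits (real 6, highest other 10), 21 of 100 splits (real 6, highest other 10) and 31 of 84 splits (real 4, highest other 9) for PLT-HSC against MUL-HSC, PEM-HSC against MUL-HSC and PLT-HSC against PEM-HSC. The number of called lists therefore does not set the real groups apart from chance.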

How the results depend on the processing

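The fit without MUL-HSC replicates 1 and 2 and the removal of GC and length trends were chosen after seeing the data. The causes of the changes below were not tested unless stated. RLE and upper quartile normalization left all 8 counts as they were. Genes called in PLT-HSC against MUL-HSC, 6 in the report, numbered 11 with no filter, 13 with at least 10 CPM in 3 libraries, 4 without robust estimation, 1 with only these groups in the fit, 0 with voom, 286 with DESeq2, 1 without MUL-HSC replicates 1 and 2, and 1 to 37 leaving out 1 library. Genes called in PEM-HSC against MUL-HSC, 1 in the report, numbered 0 with detected genes as a covariate, 0 with only these groups in the fit, 224 with DESeq2 and 0 to 4 leaving out 1 library. Voom also called 1 gene there, but not Vwf. Genes called between PLT-HSC and PEM-HSC, 0 in the report, numbered 1 with voom, 133 with DESeq2 and 0 to 2 leaving out 1 library. Genes called in any group, 1 in the report, numbered 3 with no filter, 0 with the covariate, 82 with DESeq2 and 0 to 23 leaving out 1 library. The overlap, 1 in the report, was 0 with the covariate, 0 with voom, 142 with DESeq2 and 0 to 4 leaving out 1 library. Of the genes that DESeq2 called, 183 of 286, 160 of 224 and 106 of 133 had a library at 0 in 1 of the groups compared.

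Gene lists called, 6, 6 and 4 in the report, numbered 0, 0 and 0 with an estimated correlation and 3, 0 and 1 with fry. The mixed form of fry, in which members may move either way, called 9, 7 and 2 lists. It called megakaryocyte and platelet genes in each comparison (mixed adjusted p = 1.76e-05, 0.0235 and 0.0154). That list holds Vwf, as does the sort and reporter list, called in PLT-HSC and PEM-HSC against MUL-HSC (5.57e-05 and 0.000209). The mature platelet and megakaryocyte list, without Vwf, gave 0.00193, 0.559 and 0.015 in the order of the comparisons. The part of Vwf in these calls was not tested. Lymphoid-priming genes were called by the mixed form in PLT-HSC against MUL-HSC (0.0311). Other splits were not tested with it, and fry below means the form with 1 direction. Fry called the HSC identity, aged-HSC and interferon lists in PLT-HSC against MUL-HSC and mature platelet and megakaryocyte genes, higher in PLT-HSC, against PEM-HSC (adjusted p = 0.0359). The covariate gave 8 lists in the last comparison. Leaving out 1 library gave 4 to 8, 5 to 8 and 1 to 7 lists. Among the called lists the direction of the test turned once, for oxidative phosphorylation genes in PEM-HSC without MUL-HSC replicates 1 and 2 (adjusted p = 0.683, median log2 fold change 0.052). With libraries left out, medians were computed after the results were seen, and they turned in 2 further cases where the direction of the test held: cell cycle genes of PLT-HSC against PEM-HSC without PLT-HSC replicate 1 (0.0073) and ribosomal protein genes of PLT-HSC against MUL-HSC without PLT-HSC replicate 2 (-0.0059). Cell cycle genes of PEM-HSC against MUL-HSC, not called, went from a median of -0.20 to 0.34 without MUL-HSC replicates 1 and 2. Of the list calls 346 held and 53 ended.

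For named genes 1948 values kept their side of the threshold and their direction, 75 lost a call, 69 gained one and 33 turned sign. The 33 concern 14 fold changes, none of them called with or without the change, and the largest of the 14 was 0.73 in size in the report. In PEM-HSC against MUL-HSC, Itga2b stood at -1.69 with a replicate block, -0.032 with the covariate, -0.294 with voom and -0.043 without MUL-HSC replicates 1 and 2. Procr there stood at -0.124 with the block and -0.17 without those 2 libraries, Ptprc at 0.057 with the block, and Kit at -0.072 with the covariate. In PLT-HSC against MUL-HSC, Ptprc stood at -0.051 with the covariate, and Ptprc and Procr at -0.098 and -0.055 without MUL-HSC replicates 1 and 2. Cd34 between PLT-HSC and PEM-HSC stood at 0.453 with the block.

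Leaving out 1 library, the log2 fold changes that turned ran as follows. Against MUL-HSC, in PEM-HSC, Itga2b ran from -0.723 to 0.530, Procr from -0.035 to 0.207, Ptprc from -0.208 to 0.123 and Kit from -0.031 to 0.223, and in PLT-HSC, Kit ran from -0.0031 to 0.681 and Procr from -0.107 to 0.576. Between PLT-HSC and PEM-HSC, Gata1 ran from -5.87 to 0.443, Itga2b from -3.65 to 0.031, Kit from -0.112 to 0.579, Ly6a from -0.451 to 0.715, Slamf1 from -0.134 to 0.564, Procr from -0.189 to 0.488 and Cd34 from -0.638 to 0.035.

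Replicate numbers did not pair the libraries: same-numbered libraries of different groups correlated at -0.13 to 0.05 in their deviations, and 1 of 11 correlated best with its own number. With a replicate block the counts were 2 genes in PLT-HSC against MUL-HSC, 0 in PEM-HSC against MUL-HSC, 0 in any group and 0 in the overlap. Against MUL-HSC, the block ended the calls of Vwf in PEM-HSC (adjusted p = 0.0543, log2 fold change 3.06), of Phf11d (0.554, 2.01), Ctnnal1 (0.156, 3.26), Mef2c (0.414, 1.23) and Otos (0.156, -2.61) in PLT-HSC, with folds near those of the report, and of ribosomal protein genes in PLT-HSC (0.339). Robust estimation does not apply to the list tests, and DESeq2 gives none. The floor of 3 counts lay at 0.183 CPM or below in every library, so depth limits only genes near that level.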

Other observations

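All tests in this part were set before their results were seen, and the values of Hox, Cd68 and Nfkbia are described after being seen. MUL-HSC libraries were uneven in more than 1 list. Hox genes lay at -2.52 and -1.54 log2 units from the mean of all libraries in MUL-HSC replicates 1 and 2, and HSC identity genes at -1.25 and -0.67, where the other 2 MUL-HSC libraries lay at -0.25 or above for HSC identity. Adjusted over their lists alone, Cd68 was higher in PLT-HSC (128 against 14.1 CPM) and in PEM-HSC (79.6 against 14.1 CPM), and Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, was higher in PLT-HSC (299 against 175 CPM) and in PEM-HSC (306 against 175 CPM). Neither passed over all genes.

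A hypothesis was that the groups separate genes completely, with no overlap of libraries, more often than other splits of the same libraries do. The data did not bear it out. PLT-HSC and MUL-HSC were separated by 826 of 12536 genes, where chance gives 5.71%, and 9 of 35 splits gave as many (highest other 1545). PEM-HSC and MUL-HSC were separated by 189 genes (chance 0.952%), and 8 of 100 splits gave as many (highest other 335). PLT-HSC and PEM-HSC were separated by 269 genes (chance 2.38%), and 35 of 84 splits gave as many (highest other 591).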
